A study of Antheraea pernyi with 6 samples.

How the data were processed

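RNA was sequenced from haemolymph, the insect's blood with its circulating haemocytes, of the Chinese oak silkmoth Antheraea pernyi. Per the labels, RNA was taken with Trizol from haemolymph frozen on dry ice and sequenced on an Illumina HiSeq. There were 3 samples from insects infected with Antheraea pernyi nucleopolyhedrovirus (ApNPV, a baculovirus, that is, a large DNA virus of insects) and 3 control samples. The stage of the insects, the dose and the time after infection were not given in the sources used here.

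The authors deposited 1 table for the whole series, with 50126 features. Each feature is an assembled gene of a de novo transcript assembly, named in the style of the Trinity assembler, and its length in bases stands beside it, from 201 to 16820 with a median of 406. The values are in TPM, a length-corrected share of the transcripts of a library on a fixed total, as judged from the deposited columns, which have 2 decimals and sum to the same total within rounding. Salmon, cutadapt, FastQC and edgeR are named in the submitters' processing notes, without versions or order. The assembler's settings, the read filters and any normalisation between libraries are not given in the sources used here. The columns for treated libraries are headed H_T with a number and those for control libraries H_C with a number. They were taken as the ApNPV and control samples of the same number. That the letter T stands for the infected arm is an inference from its being the only other arm.

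TPM values keep no sequencing depth, so the depth of each library is unknown and no counting intervals or detection limits are given. Instead, precision was judged from the spread between the 3 replicates. The median coefficient of variation of features with a mean of at least 10 TPM was 19.6% in the ApNPV group and 9.48% in the control group. At a mean of at least 1000 TPM it was 2.50% and 1.95%. Nothing in the labels says that the 3 samples of a group came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical. Features are often fragments of a gene, and Salmon divides reads between similar features, so levels of multigene families such as serpins, cecropins, tubulins and ubiquitin are uncertain for each single feature. Some baculovirus features are long, such as those named very late expression factor 1 (5443 bases) and viral cathepsin (7031 bases). They may span more than 1 viral gene, so their TPM cannot be credited to the named gene alone.

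The table pairs features with a protein name from an NR-type search for 16194 features and from Swiss-Prot for 9610. A feature was named by the NR entry, then by Swiss-Prot (191 further features), then by the KEGG or eggNOG description (245), which left 33496 features without a name. An informative name, not hypothetical or uncharacterised, was held by 12023. No reference genome was used, so no coordinates are given. Ribosomal RNA could not be identified without sequences, so any that the table holds is part of the summed TPM and of each rescaling.

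The main test was fixed before the data were examined. Each library was divided by its median ratio to the geometric mean library over the 9717 features above 0 in all 6 libraries (size factors 1.09, 1.09 and 1.11 for ApNPV and 0.959, 0.965 and 0.983 for control). Features at 1 TPM or more in at least 3 libraries were kept, 12293 in all. The test was limma 3.58.1 (R 4.3.3), with an empirical Bayes trend, on log2(TPM / size factor + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are therefore on the log2(TPM + 1) scale, which understates changes of features with low values. The design had been written for either counts or TPM. As the values are TPM, no count model was used. Means ± SD are of the deposited TPM values, with n = 3 per group.

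Baculovirus transcripts were those whose protein name matched a fixed rule of virus and virion terms (47 features). A second set took every feature whose Swiss-Prot entry names a baculovirus as source organism (88 features, among them all 47), since no NR-type name was that of a virus. The share of summed TPM was compared by an exact two-sided permutation test, which cannot give a p below 0.1 with 3 against 3 samples. A total of 30 gene and marker lists were fixed as name patterns before the data were examined, and the 28 with at least 5 tested members were tested with camera (limma, preset inter-gene correlation of 0.01), with adjustment over these lists. The same lists were tested with an estimated correlation and with fry. The lists covered baculovirus transcripts, antimicrobial peptides, pattern recognition, Toll, IMD and JAK-STAT signalling, melanisation and CLIP proteases, serpins and protease inhibitors, RNA interference, apoptosis, autophagy and lysosome, heat shock proteins and chaperones, phagocytosis, adhesion and cytoskeleton, cytosolic ribosomal proteins, DNA replication and cell cycle, mitochondrial respiration, glycolysis and TCA cycle, antioxidants and glutathione, detoxification enzymes, proteasome and ubiquitin, histones, juvenile hormone and ecdysone, cuticle and chitin, lipid transport, transposable elements, and markers of haemocytes, fat body, muscle, silk gland, midgut, epidermis and trachea, and the nervous system.

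Features named in the text follow a rule fixed in advance. It takes the 10 largest rises and the 10 largest falls among features past the threshold that had no overlap between groups, a mean of at least 10 TPM over the 6 libraries, an informative name and no match to the virus rule, with 1 feature per protein name. It adds the 6 baculovirus transcripts with the highest ApNPV mean. From each list it takes the 2 with the highest overall mean among members past the threshold in each direction, or the 2 with the highest mean where none passed. Features outside this rule are marked as chosen after their values were seen.

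The test was run first on simulated values for the same 12293 features and 3 against 3 libraries. The 200 changed features were drawn only from those with a mean above about 10 TPM. Recovery was therefore not measured at lower levels, where most tested features lie. The test recovered 58.2% of features changed by 1 on the log2 scale, 97.0% of those changed by 2 and 100% of those changed by 3. Of its calls, 9.09% were false. Alternatives fixed in advance were the replicate number as a block, the values as deposited, host features rescaled to the same host total, quantile normalisation, pseudocounts of 0.1 and 0.5 in place of 1, no filter, a filter of 5 TPM, robust and array-weighted limma, an added minimum log2 change of 1, and each replicate left out. Removal of the features with a baculovirus as source organism, with and without rescaling, a median ratio over features with a mean of at least 10 TPM, Swiss-Prot names in place of uninformative NR names, and the pattern recognition list without thioesterases were added after seeing the data. Scripts used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.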

Results

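Haemolymph transcript levels were compared between insects infected with ApNPV and control insects, to describe the cellular and humoral immune response of Antheraea pernyi to this virus. There were 3 libraries per group. The values were TPM, which sum to the same total in each of the 6 libraries, so sequencing depth could not be read from them. Between 16210 and 17431 of the 50126 assembled genes, called features here, were above 0 in the ApNPV libraries, against 22807 to 23658 in the control libraries. The 100 most abundant features held 68.5% to 68.7% of each ApNPV library and 70.9% to 71.3% of each control library. Across features, the Pearson correlation of log2 values was 0.817 to 0.823 between ApNPV replicates, 0.921 to 0.928 between control replicates and 0.654 to 0.669 between groups. The first principal component, with 59.6% of the variance, separated the groups.

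Viral transcripts made up a large part of the infected libraries. Transcripts recognised as baculovirus by name held 17.9% ± 0.312 (SD, n = 3) of expression in the ApNPV group and 0.00243% ± 0.000375 (n = 3) in the control group. All 41 tested baculovirus transcripts were higher in the ApNPV libraries, with a median log2 change of 10.30 (limma; 41 when adjusted over the list alone). The rest of the 47 did not reach 1 TPM in at least 3 libraries. Most tested ones lay under 1 TPM in control, so only their ApNPV values could bring them past this filter. Their direction was thus largely fixed in advance. The most abundant feature of baculovirus source, serine/threonine-protein kinase 1 at 31460 ± 478 TPM, fell outside the name rule (chosen after its value was seen). Under the name rule, the 6 most abundant baculovirus transcripts began with the uncharacterised ORF11 product (TRINITY_DN11220_c0_g1). It stood at 27602 ± 717 TPM, against 3.38 ± 0.501 TPM in control. The occlusion-derived virus envelope protein E25, a component of the virion that is embedded in occlusion bodies, stood at 18516 ± 154 TPM. The late expression factor 2, which acts in viral DNA replication and late transcription, stood at 18399 ± 497 TPM. The uncharacterised ORF139 product stood at 17717 ± 117 TPM, the spheroidin-like protein at 14988 ± 102 TPM and the p48 protein at 9930 ± 414 TPM, with control means of 1.04 to 4.26 TPM for these 5. All are levels of features, which may span more than 1 viral gene. When every feature with a baculovirus as its Swiss-Prot source organism was counted, the share was 24.6% ± 0.421 in the ApNPV and 0.00745% ± 0.000795 in the control group, where features that infection did not raise made up 56.4% of it. The difference of 17.9 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow. Features that were not annotated as baculovirus and had no informative name held 31.3% ± 0.326 of ApNPV and 31.6% ± 0.0866 of control expression. Some of these may be viral, as 16 without any name held 1.97% of ApNPV and 0.000303% of control expression. What the features of this set are was not determined. Some abundant ones rose, such as a hypothetical protein (TRINITY_DN17925_c0_g1, protein NLRC3 in Swiss-Prot) from 9525 ± 123 to 30984 ± 643 TPM.

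**Figure D1:**
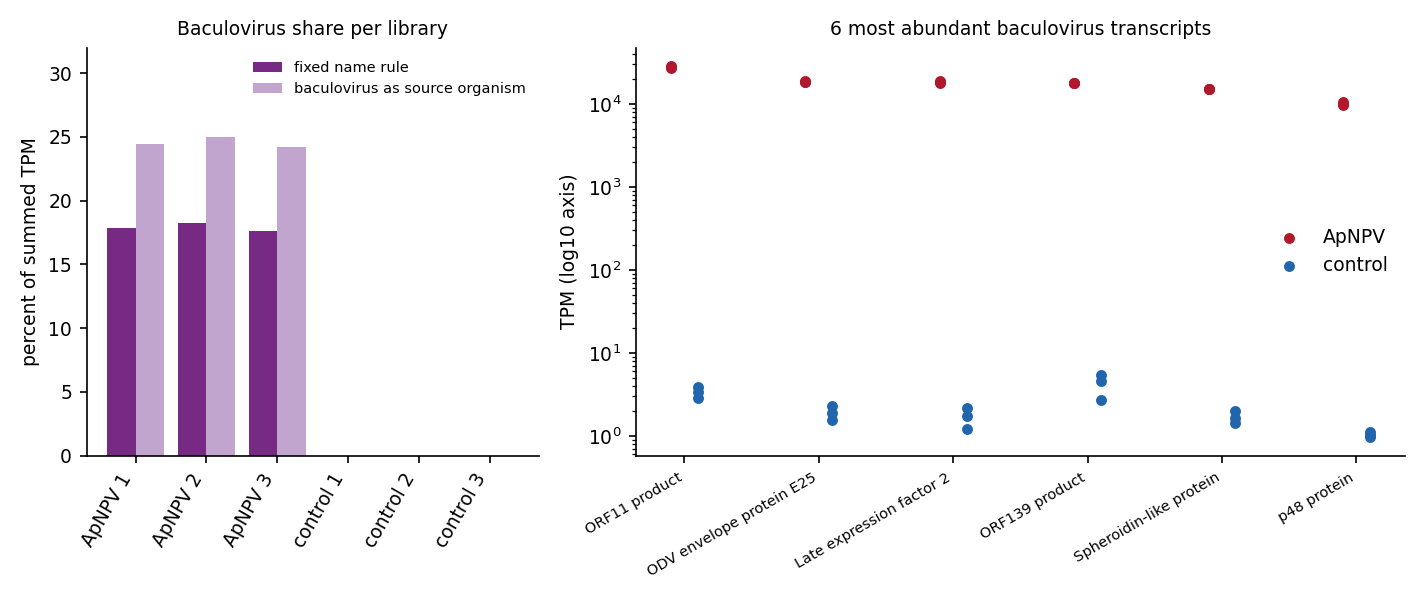
Percent of summed TPM held in each of the 6 libraries by baculovirus transcripts under the fixed name rule (dark bars) and by features with a baculovirus as source organism (light bars), on the left, and TPM on a log10 axis of the 6 most abundant baculovirus transcripts under the name rule, 1 point per library, on the right. By the name rule the 3 ApNPV libraries lie between 17.6% and 18.2%, and the control libraries at 0.00272% or below.

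Infection was accompanied by changes in 2982 of the 12293 features tested (24.3%), of which 885 were higher and 2097 lower in the ApNPV libraries (limma, adjusted p under 0.05). Among features with a mean of at least 10 TPM, 511 were higher and 888 lower of 2664. In the deposited values, before any rescaling, the 2 groups did not overlap for 39.8% of tested features, where chance gives 10%. Viral transcripts take up part of each ApNPV library, which can by itself separate the groups in these values. The split by direction rested on the scaling. The median change of all tested features was -0.13 on the log2 scale in the main test and 0.26 after the features with a baculovirus as source organism were removed and the rest rescaled to the same total, a shift of 0.40, which gave 1865 higher and 1555 lower features. With host features by the name rule rescaled in the same way, 1606 were higher and 1654 lower. With the median ratio over features of at least 10 TPM, 1206 were higher and 1865 lower. Its size factors were 0.983 to 0.999 for ApNPV and 1.01 to 1.03 for control, opposite in order to those of the main test. The number of higher features fell to 562 without control replicate 1, 559 without control replicate 2 and 566 without control replicate 3.

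**Figure D2:**
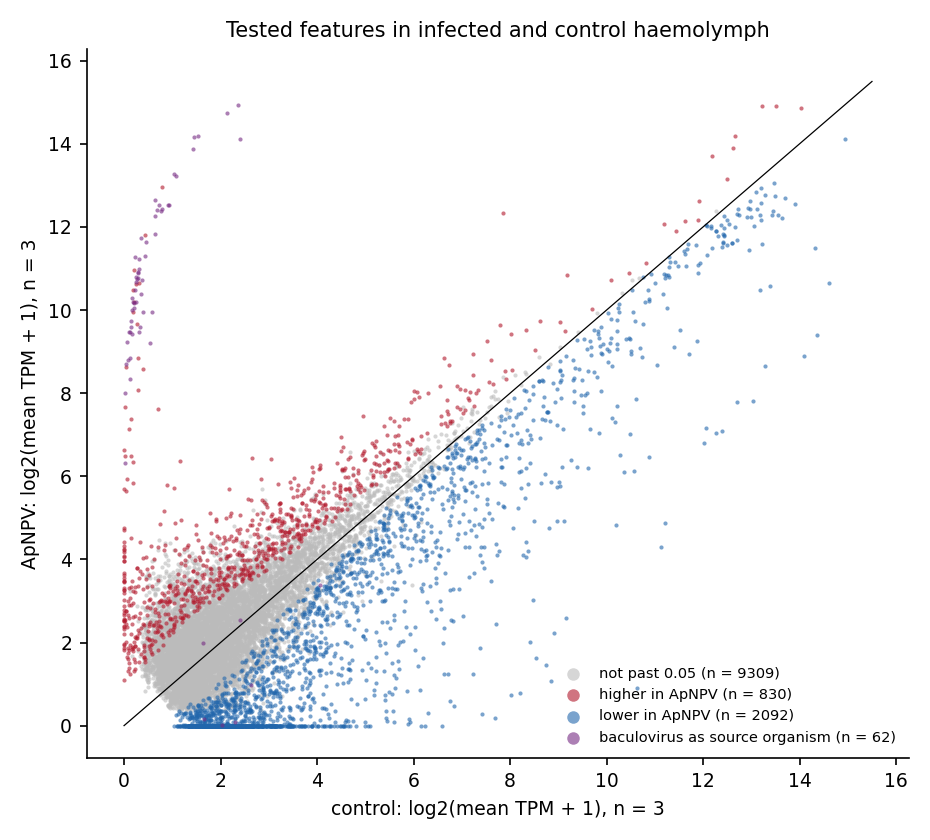
Mean levels of the 12293 tested features, as log2(mean TPM + 1) over 3 control libraries (horizontal axis) and 3 ApNPV libraries (vertical axis), with a line at equal levels. The 62 features with a baculovirus as source organism, in purple, lie mostly at the upper left, and 2092 other features are lower and 830 higher in the ApNPV libraries.

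Genes of melanisation and antimicrobial defence were among the 10 largest falls of features with an informative name, taking 1 feature per protein name. Prophenoloxidase (TRINITY_DN13346_c1_g1), the zymogen of the enzyme that makes melanin, stood at 1.73 ± 0.705 TPM in the ApNPV and 425 ± 6.998 TPM in the control group, a log2 change of -7.44 (SE 0.188, limma adjusted p = 5.9e-07). A second prophenoloxidase feature (TRINITY_DN11559_c2_g1), left out of the ranking as a repeated name, fell from 340 ± 7.03 to 3.03 ± 1.18 TPM. The small heat shock protein G7 (TRINITY_DN9956_c0_g2) fell from 2378 ± 18.7 to 28.2 ± 5.73 TPM and the diapause associated protein 2 from 260.2 ± 3.93 to 0.667 ± 0.351 TPM. Moricin B3 (TRINITY_DN15519_c0_g4), an antimicrobial peptide, was listed at 0 in the 3 ApNPV libraries against a mean of 95.9 ± 19.5 TPM in control. A second moricin B3 feature (TRINITY_DN10025_c0_g1), at 15.52 ± 18.1 TPM in ApNPV and 34.1 ± 7.67 TPM in control, did not pass (adjusted p = 0.13). A lectin (TRINITY_DN13356_c1_g3) fell from 113 ± 1.801 to 0.383 ± 0.276 TPM and a lectin 3 (TRINITY_DN14656_c3_g3) from 107 ± 8.31 to 0.507 ± 0.515 TPM. A cystathionine gamma-lyase (TRINITY_DN13132_c1_g9), an enzyme of cysteine synthesis, fell from 166 ± 4.55 to 2.62 ± 2.13 TPM. A putative secreted peptide 30, a putative integumental esterase and the moricin-like peptide D completed these 10 falls, whose log2 changes ran from -7.44 to -5.76, with adjusted p of at most 0.0081.

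Of the 10 largest rises, 9 had a baculovirus as their Swiss-Prot source organism although their NR-type names were those of animal proteins. They included an XIAP-like ubiquitin ligase name at 5925 ± 303 TPM (apoptosis inhibitor 1 in Swiss-Prot), a chitinase A name at 5501 ± 99.6 TPM and a fibroblast growth factor 7 name at 1066 ± 45.7 TPM, with control means of 0.733 TPM or less. The others had the names of a cap specific mRNA, a dual specificity phosphatase, a proliferating cell nuclear antigen, a polynucleotide kinase, a centromere-associated protein E and a DNA polymerase delta. The tenth was named only antirepressor, at 3601 ± 79.6 TPM against 0.353 ± 0.0971 TPM. It had no source organism, and its feature (TRINITY_DN9586_c0_g1) shared an assembly cluster with the baculovirus features E25 (TRINITY_DN9586_c0_g2) and helicase P143 (TRINITY_DN9586_c0_g3). The antirepressor may therefore be viral, which was not tested. A shared cluster alone does not mark a feature as viral. The 70 kDa heat shock cognate (TRINITY_DN15649_c0_g1), at 12777 TPM in control, shared one with baculovirus features such as TRINITY_DN15649_c0_g3. The same ranking without features of baculovirus source was made after the values were seen. It was led, after the antirepressor, by a microvitellogenin feature (TRINITY_DN16066_c0_g3), a small plasma protein of moths, which rose from 0.633 ± 0.194 to 196 ± 19.9 TPM (log2 change 6.77, SE 0.164, limma adjusted p = 4.8e-07). A Dscam2-like adhesion molecule rose from 0.0333 ± 0.0577 to 49.0 ± 3.90 TPM and a putative transposase from 1.22 ± 0.875 to 81.8 ± 9.99 TPM. The dUTP nucleotidohydrolase, which keeps uracil out of DNA, rose from 6.12 ± 2.14 to 60.3 ± 9.28 TPM and a geminin, a regulator of replication licensing, from 3.30 ± 1.03 to 30.8 ± 8.41 TPM. A feature named hemolymph protein, a zinc finger MYM-type protein, an allatostatin-A receptor and a tubulin beta chain made up the rest, with log2 changes of at least 2.72 over the 10.

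**Figure D3:**
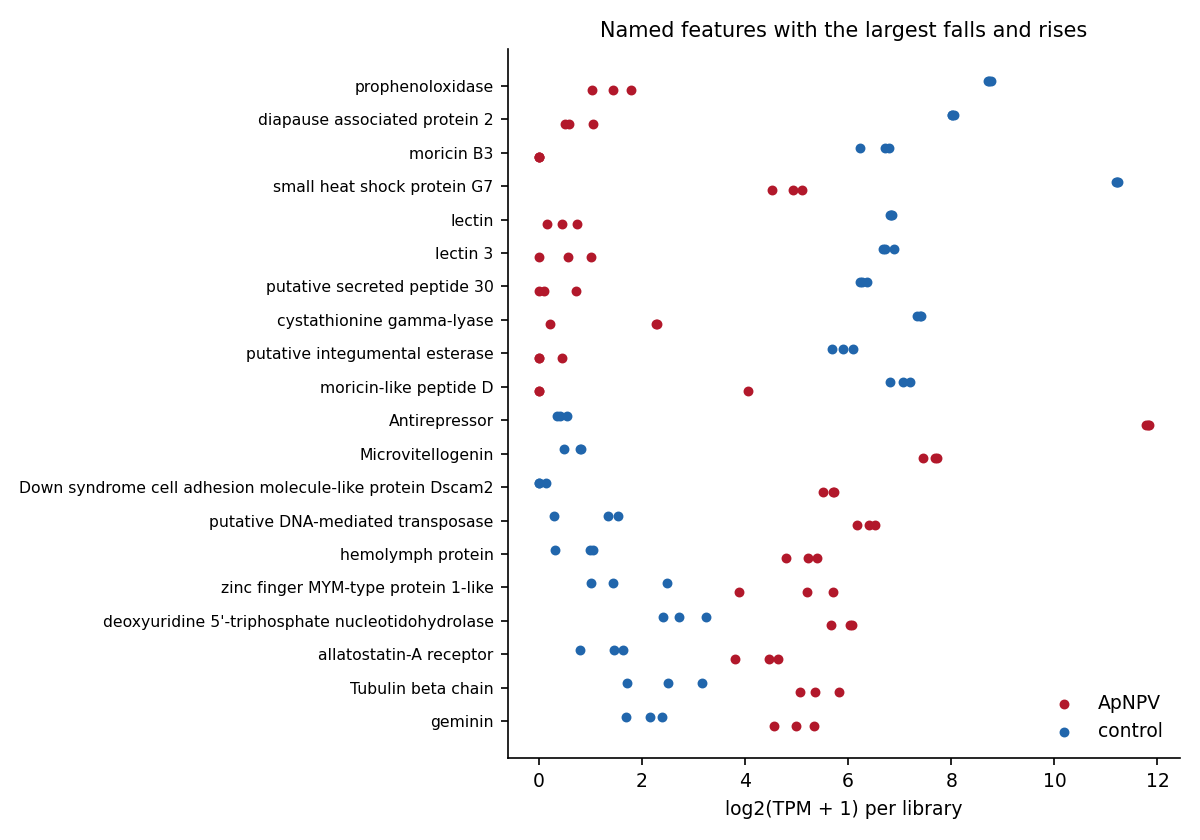
Levels of the 10 largest falls and the 10 largest rises without baculovirus source, with 1 feature per protein name, as log2(TPM + 1) in each of the 6 libraries, with ApNPV in red and control in blue. The groups do not overlap for any of these 20 features, and log2 changes run from -7.44 for prophenoloxidase to 11.24 for the antirepressor. The antirepressor has no named source organism and may be viral.

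Of the 28 gene lists tested, 14 passed the threshold, 12 of them lower in ApNPV libraries and 2 higher (camera with the preset correlation). With an estimated correlation 9 passed, and fry, which asks only whether a list moves one way on balance, called 24. Antimicrobial peptides fell in 14 of 19 tested members and rose in 0 (0 and 14 when adjusted over the list alone), with a median log2 change of -2.70 (camera adjusted p = 9.8e-08). Cecropin-B fell from 1179 ± 58.0 to 27.4 ± 3.59 TPM and a lysozyme, which cuts bacterial cell walls, from 807 ± 12.9 to 140.2 ± 20.3 TPM. Serpins and protease inhibitors fell in 25 of 29 members (26 when adjusted over the list alone), with a median of -2.74 (camera adjusted p = 9.3e-17). A pacifastin-type inhibitor fell from 17374 ± 494 to 475 ± 72.8 TPM. Serpin 2, of the family that restrains haemolymph proteases, fell from 10771 ± 83.7 to 1540 ± 12.7 TPM. Melanisation and CLIP proteases fell in 21 of 24 members and rose in 1 (21 and 1 when adjusted over the list alone), with a median of -2.21 (camera adjusted p = 6.1e-10). Hemolymph proteinase 18 fell from 332 ± 2.82 to 110.03 ± 16.0 TPM. Hemolymph proteinase 10 rose from 0.690 ± 0.397 to 4.21 ± 0.442 TPM, a call lost without control replicate 1 or 2 (adjusted p = 0.073 and 0.057). These 3 lists also passed with an estimated correlation (adjusted p = 0.018, 0.015 and 0.015), and under each scaling their medians stayed at -1.78 or below.

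The pattern recognition list fell in 12 of 20 members and rose in 2 (12 and 3 when adjusted over the list alone), with a median of -1.73 (camera adjusted p = 0.015; adjusted p = 0.091 with an estimated correlation). The name pattern also drew in 5 thioesterases, which are not pattern recognition proteins and of which 2 fell. Without them, a step chosen after the data were seen, 10 of 15 members fell and 2 rose, with a median of -1.87 (camera adjusted p = 0.0081). Hemolin, an immunoglobulin-type protein that binds microbial surfaces, fell from 4918 ± 7.04 to 131 ± 65.1 TPM and a hemolin-like protein from 398 ± 11.3 to 56.0 ± 4.13 TPM. The members that rose were the Dscam2-like feature and the peptidoglycan recognition protein-D, at 1.77 ± 1.51 in control and 14.8 ± 11.05 TPM in ApNPV libraries, whose adjusted p of 0.044 rose above the threshold when any 1 library was left out (0.052 to 0.12). The Toll, IMD and JAK-STAT list, at a median of -0.34, did not pass (camera adjusted p = 0.40). It fell in 3 of 18 members and rose in 0 (3 and 0 when adjusted over the list alone). Spatzle, the ligand of the Toll receptor, fell from 29.8 ± 2.25 to 3.47 ± 1.78 TPM. A toll-like protein stood at 14.9 ± 0.639 in control and 8.81 ± 1.48 TPM in ApNPV libraries, a call lost under both host rescalings (adjusted p = 0.13 and 0.24) and without any 1 control replicate (0.051 to 0.065). RNA interference, with 1 member higher and 1 lower of 8 (the same counts when adjusted over the list alone), did not pass (camera adjusted p = 0.65), its median of -0.05 and its test differing in sign. Translin rose from 40.8 ± 3.996 to 67.9 ± 1.85 TPM. R2D2, a partner of Dicer, stood at 12.4 ± 1.76 in control and 5.48 ± 1.67 TPM in ApNPV libraries, a call lost under both host rescalings (adjusted p = 0.072 and 0.10) and without control replicate 2 or 3 (0.072 and 0.079). In the apoptosis list 1 of 25 members rose and 4 fell (1 and 4 when adjusted over the list alone; camera adjusted p = 0.60). Programmed cell death protein 5 rose from 47.2 ± 1.54 to 108 ± 9.54 TPM and bax inhibitor 1 fell from 228 ± 3.09 to 74.3 ± 1.37 TPM.

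Markers of haemocytes fell in 22 of 29 members and rose in 0 (24 and 0 when adjusted over the list alone), with a median of -2.22 (camera adjusted p = 9.4e-12; adjusted p = 0.018 with an estimated correlation). Besides prophenoloxidase, which the melanisation list also holds, annexin IX-B fell from 857 ± 20.8 to 363 ± 16.7 TPM. The fat body list, with 1 member higher and 5 lower of 10 (1 and 7 when adjusted over the list alone), did not pass (camera adjusted p = 0.081). It passed as lower under quantile normalisation (0.047), with Swiss-Prot names (0.043) and without ApNPV replicate 2 or 3 (0.045 and 0.039). Its microvitellogenin features moved in both directions, with TRINITY_DN14373_c1_g2 falling from 211 ± 9.95 to 16.1 ± 5.34 TPM. The muscle list did not pass either (camera adjusted p = 0.12), with 7 members higher and 6 lower of 18 (10 and 6 when adjusted over the list alone). With the filter of 5 TPM its median was -1.67 (camera adjusted p = 0.75). Muscle-specific protein 20 rose from 0.367 ± 0.297 to 10.5 ± 2.48 TPM and a troponin I, of the contractile thin filament, from 0.163 ± 0.153 to 8.28 ± 1.27 TPM. Both lay under 1 TPM in control, so only their ApNPV values could bring them past the filter. Their direction was thus largely fixed in advance. Tropomyosin-1, which has non-muscle forms too, fell from 169.7 ± 16.9 to 55.5 ± 17.7 TPM. Epidermis and trachea (2 higher and 3 lower of 11, camera adjusted p = 0.52) and the nervous system (0 and 3 of 12, camera adjusted p = 0.32) did not pass (3 and 3, and 1 and 3, when adjusted over the list alone). Of the midgut markers 4 were tested and 2 fell (2 when adjusted over the list alone), and of the silk gland markers 0 were tested.

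Detoxification enzymes fell in 16 of 29 members and rose in 0 (19 and 0 when adjusted over the list alone), with a median of -1.21 (camera adjusted p = 2.4e-06; adjusted p = 0.018 with an estimated correlation). A juvenile hormone esterase-related protein fell from 726 ± 27.8 to 183 ± 25.3 TPM. The juvenile hormone epoxide hydrolase, which degrades juvenile hormone, stood at 5555 ± 21.2 in control and 4016 ± 138 TPM in ApNPV libraries, a call lost after removal of baculovirus-source features and rescaling (adjusted p = 0.13). Autophagy and lysosome genes fell in 16 of 30 members and rose in 0 (18 and 0 when adjusted over the list alone), with a median of -0.88 (camera adjusted p = 9.5e-07; adjusted p = 0.018 with an estimated correlation). A lysosomal thiol reductase of the gamma-interferon-inducible type fell from 1650 ± 17.3 to 542 ± 31.5 TPM.

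Cytosolic ribosomal proteins were lower in 58 of 75 members and higher in 7 (59 and 7 when adjusted over the list alone), with a median of -0.49 (camera adjusted p = 6.0e-21; adjusted p = 0.059 with an estimated correlation), although the direction turned after removal of baculovirus-source features and rescaling, to a median of 0.09, with the call lost (adjusted p = 0.83). The 40S protein S21 fell from 15242 ± 1000.4 to 6011 ± 171 TPM and the 60S protein L44 rose from 5774 ± 87.3 to 9132 ± 174 TPM. Mitochondrial respiration was lower in 45 of 86 members and higher in 6 (48 and 6 when adjusted over the list alone), with a median of -0.52 (camera adjusted p = 9.5e-09; adjusted p = 0.015 with an estimated correlation), a median that turned to 0.05 after the same rescaling, with the call lost (adjusted p = 0.14). Cytochrome c oxidase subunit III, encoded in mitochondrial DNA, fell from 11100 ± 254 to 5343 ± 31.3 TPM. Glycolysis and TCA cycle (12 lower and 3 higher of 36, camera adjusted p = 0.013), antioxidants and glutathione (20 lower and 1 higher of 46, camera adjusted p = 0.015) and phagocytosis, adhesion and cytoskeleton (27 lower and 4 higher of 107, camera adjusted p = 0.029) also passed, with the same counts when adjusted over the list alone except for 29 lower and 5 higher in the last. Their calls ended with an estimated correlation (adjusted p = 0.083, 0.079 and 0.18) and after both host rescalings. Their medians of -0.39, -0.34 and -0.34 turned to 0.09, 0.19 and 0.04 after removal of baculovirus-source features and rescaling. The last call also ended under quantile normalisation (camera adjusted p = 0.067) and without ApNPV replicate 2 (0.069). That of antioxidants also ended with the values as deposited (0.089), under quantile normalisation (0.061), with the filter of 5 TPM (0.065) and with the median ratio over features of at least 10 TPM (0.13). That of glycolysis also ended with this median ratio (0.057), without a filter (0.075) and with the filter of 5 TPM (0.082). Among their members, a trehalose transporter fell from 239 ± 4.49 to 87.8 ± 5.84 TPM, thioredoxin from 629 ± 3.36 to 319.9 ± 34.1 TPM and a tubulin beta-1 chain from 1403 ± 10.5 to 637 ± 25.2 TPM. In the glycolysis list, glyceraldehyde-3-phosphate dehydrogenase 2 also fell, from 539 ± 11.5 to 346 ± 44.5 TPM. Enolase rose from 151 ± 6.07 to 207 ± 8.63 TPM and triosephosphate isomerase from 128 ± 5.59 to 184 ± 17.99 TPM. The 26 kDa ferritin subunit rose from 1410.1 ± 17.0 to 1907 ± 44.6 TPM.

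DNA replication and cell cycle was the host list that rose. It was higher in 14 of 46 members and lower in 0 (16 and 0 when adjusted over the list alone), with a median of 0.62 (camera adjusted p = 7.3e-08; adjusted p = 0.028 with an estimated correlation). Its most abundant members past the threshold had a baculovirus as source organism. A proliferating cell nuclear antigen name (LEF-8, a probable RNA polymerase subunit, in Swiss-Prot) stood at 708 ± 34.5 TPM in ApNPV libraries. A DNA polymerase delta name (a viral DNA polymerase in Swiss-Prot) stood at 417 ± 7.45 TPM. Without all features of baculovirus source the list still passed (median 0.61, camera adjusted p = 8.2e-07). Other members were chosen after the values were seen. A proliferating cell nuclear antigen without baculovirus source, the sliding clamp of DNA polymerase, rose from 57.7 ± 5.35 to 166 ± 6.43 TPM. Thymidylate synthase rose from 11.1 ± 1.79 to 54.2 ± 11.2 TPM and the licensing factor Mcm7 from 10.1 ± 0.556 to 31.4 ± 2.92 TPM. Heat shock proteins and chaperones went both ways, with 19 higher and 16 lower of 76 (24 and 18 when adjusted over the list alone), and did not pass (camera adjusted p = 0.33), the median of -0.01 and mean of -0.19 differing in sign from the test. The list passed as higher after both host rescalings (camera adjusted p = 0.044 and 0.021). The 70 kDa heat shock cognate fell from 12777 ± 163 to 4764 ± 272 TPM, while heat shock protein 90 rose from 263 ± 4.005 to 378 ± 2.36 TPM. The proteasome and ubiquitin list, with 18 higher and 17 lower of 132 (the same when adjusted over the list alone), did not pass (median 0.06, camera adjusted p = 0.12). It passed as higher under the values as deposited (adjusted p = 0.032), quantile normalisation (0.038), the filter of 5 TPM (0.045), the median ratio over features of at least 10 TPM (0.024) and both host rescalings (0.0018 and 0.00099).

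The other lists did not pass. Lipid transport and metabolism had 1 member higher and 14 lower of 50 (camera adjusted p = 0.12). A triacylglycerol lipase fell from 75.8 ± 0.908 to 17.6 ± 2.08 TPM. Cuticle and chitin had 3 higher and 3 lower of 15 (camera adjusted p = 0.14, and 0.039 without ApNPV replicate 3), 1 of the higher ones being the chitinase A name of baculovirus source. The cuticle protein CPH43 fell from 1192 ± 3.72 to 727 ± 6.28 TPM. Transposable elements had 7 higher and 9 lower of 63 (camera adjusted p = 0.63). Histones had 1 higher and 1 lower of 5 (camera adjusted p = 0.66). Histone H3.3 fell from 1548 ± 45.3 to 849 ± 10.9 TPM and histone H2A.V rose from 238 ± 15.2 to 371 ± 22.6 TPM. Juvenile hormone and ecdysone had 0 higher and 1 lower of 8 (camera adjusted p = 0.35). When adjusted over the list alone, these lists counted 2 and 14, 4 and 3, 8 and 11, 1 and 1, and 0 and 1 members higher and lower.

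**Figure D4:**
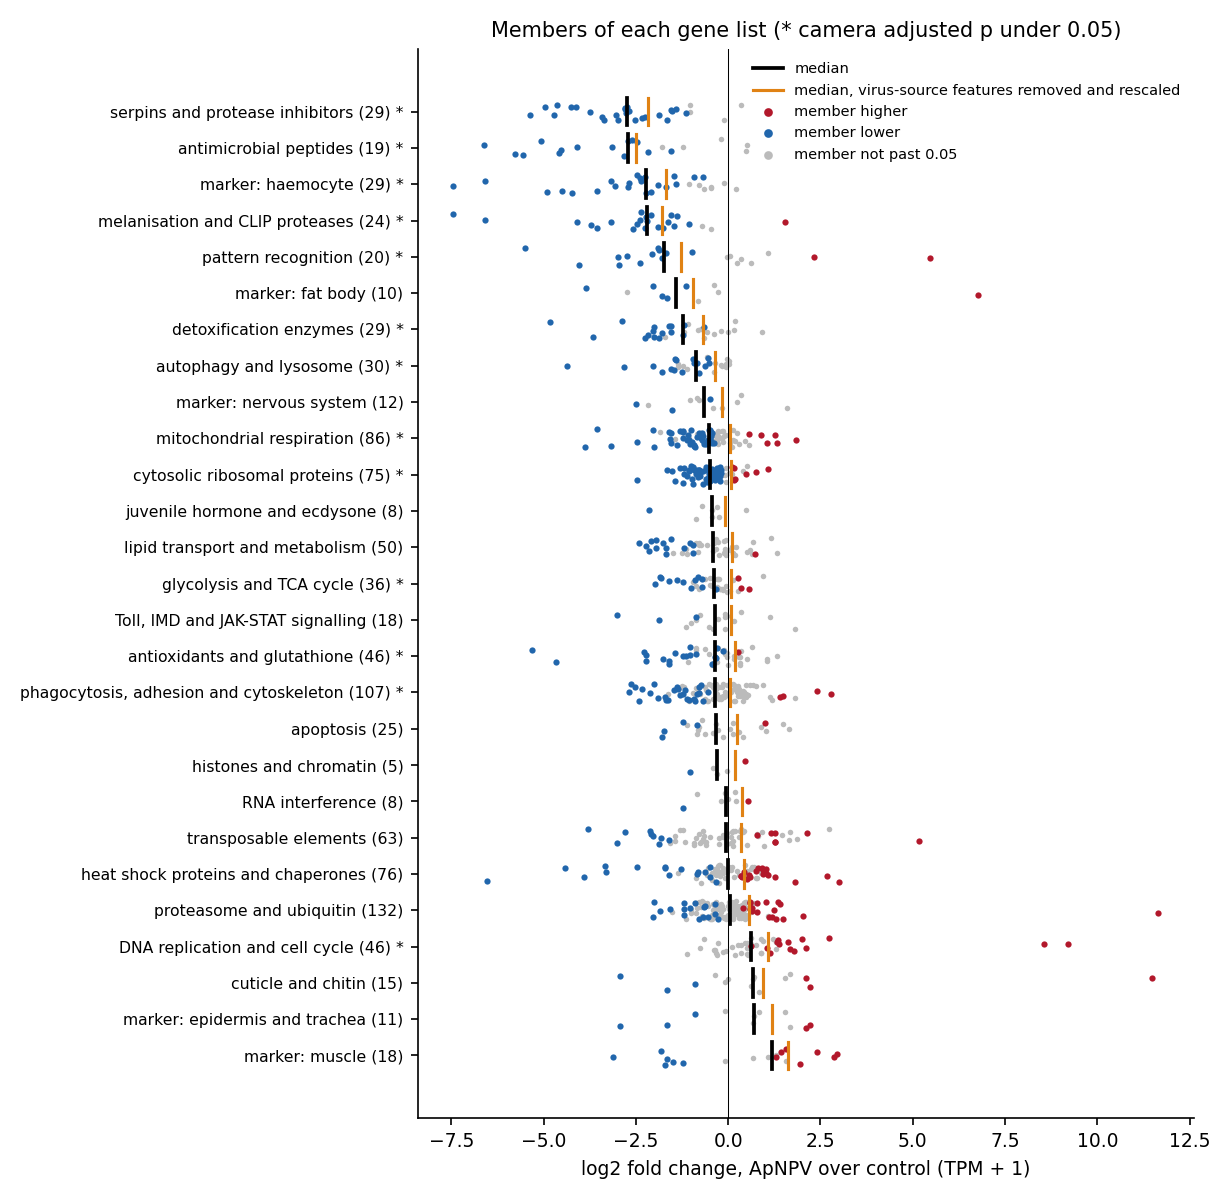
Log2 fold changes (TPM + 1 scale, ApNPV over control) of the tested members of each gene list, 1 point per feature, with the number of members in parentheses, black bars at list medians, orange bars at medians after removal of baculovirus-source features and rescaling, and an asterisk where the camera adjusted p is under 0.05. The serpin, antimicrobial peptide, haemocyte and melanisation lists have medians of -2.74, -2.70, -2.22 and -2.21, and the ribosomal and mitochondrial medians of -0.49 and -0.52 turn to 0.09 and 0.05 after the rescaling, where neither list passed.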

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

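All tests of explanations in this part were chosen after the results they bear on had been seen. A signal appeared in an annotation column that the naming rule did not use. Features whose Swiss-Prot source organism is a baculovirus but whose NR-type name is that of an animal protein held 6.66% ± 0.109 (SD, n = 3) of expression in the ApNPV libraries and 0.00502% ± 0.000425 in the control libraries, where much of it lay in features that infection did not raise. Among the 21 of them that were tested, 14 were higher and 5 lower in ApNPV libraries. The most abundant, chosen after its value was seen, had the name of serine/threonine-protein kinase 1 of baculoviruses, at 31460 TPM. It has 4720 bases and may span more than 1 viral gene. Beyond these, 16 features without any name had a mean of at least 100 TPM in ApNPV and under 1 TPM in control libraries, and held 1.97% ± 0.0561 of ApNPV expression. No biological explanation was tested for these values.

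Baculovirus transcripts were also above 0 in the control libraries, at a median of 0.0116% of their ApNPV level over the 51 features of at least 100 TPM in ApNPV libraries and above 0 in each control library. The range was 0.00499% to 0.0482%. One candidate explanation is carry-over of a fixed fraction of reads between libraries, which predicts that deviations from a single ratio are not shared between control libraries. Their median correlation was 0.546, between the bounds of 0.3 and 0.6 set for and against it. Low-level infection of the control animals was the other, and the highest control share by the name rule was 1.35 times the lowest, between bounds of 1.1 and 2. Both remain open and cannot be told apart here, because both values lie between their bounds and, with depth unknown, the counting error of the control levels is unknown.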

How the results depend on the processing

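The removal of baculovirus-source features, with or without rescaling, the median ratio over features of at least 10 TPM, the Swiss-Prot names and the pattern recognition list without thioesterases were chosen after seeing the data. The number of changed features, 2982, was 1698 without a filter, where 36867 features were tested. The number of higher features, 885, was 1606 with host features rescaled, 1865 with baculovirus-source features removed and the rest rescaled, 498 without a filter, and 559 to 881 with 1 replicate left out. The number of lower features, 2097, was 1200 without a filter and 1336 with the filter of 5 TPM, where 4627 features were tested. The number of changed lists, 14, was 9 with an estimated correlation and 24 with fry. Apart from the filters, which changed how many features were tested, the cause was not tested. Otherwise these counts stayed within 1.5 times, and the baculovirus difference stayed between 17.7 and 24.5 percentage points. Same-numbered deviations correlated at -0.0042, 0.021 and 0.0026, and differently numbered ones at -0.029 to 0.027. The replicate numbers thus gave no sign of pairing, although 3 samples per group cannot exclude it. The replicate block gave 2424 features, 632 higher and 1792 lower, and 14 lists.

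The sign of list medians changed for 12 of 27 lists after removal of baculovirus-source features and rescaling, 5 of which had passed, and for 6 of 27 with host features rescaled, 1 of which had passed. Camera's own direction turned for 6 lists, of which the ribosomal list had passed. Their medians in those settings, after removal of baculovirus-source features and rescaling, were 0.0869 for ribosomal proteins, 0.23 for apoptosis, 0.19 for histones and 0.34 for transposable elements. With host features rescaled they were 0.0889 for histones and 0.26 for transposable elements, and with the filter of 5 TPM -1.67 for muscle. Without a filter they were -0.28 for RNA interference and -0.0156 for histones, and with Swiss-Prot names -0.17 for histones, where the median kept its sign and the test alone turned. For transposable elements the test turned to lower while the median turned to higher. Of 28 lists, 14 kept camera's direction and the side of the threshold under each alternative run other than the estimated correlation and fry. Of 104 named features, 84 did so, 19 lost their call somewhere and 3 turned. Ferritin (-0.13) turned to 0.0472 with values as deposited, 0.33 with host features rescaled, 0.45 without baculovirus-source features and rescaled, and 0.0837 with the median ratio over abundant features. The ubiquitin and L40 fusion turned to 0.10 and 0.22 under the 2 rescalings, and an ELAV-like protein to 0.0753 under the second. The cause was not tested. The planned count models were not run, as the values are TPM. Depth is unknown, which leaves open whether the lower number of features above 0 in ApNPV libraries reflects depth.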

Other observations

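The tests of the haemocyte and mitochondrial patterns, the KEGG pathways and the subunit groups were chosen after the results had been seen, and the bounds for the splits of the libraries were also written then. Among KEGG pathways with at least 10 tested members, and without features of baculovirus source, 37 of 157 passed camera's threshold with the preset correlation, 14 higher and 23 lower, and 0 passed with an estimated correlation (lowest adjusted p 0.096). After removal of baculovirus-source features and rescaling, the balance turned to 17 higher and 13 lower of 30 that passed, of which 25 were also among the 37 with the same direction. Oxidative phosphorylation (median -0.55) lost its call there (adjusted p = 0.051). The lower ones of the 37 included lysosome (median log2 change -1.16, 41 of 84 members lower and 2 higher), ECM-receptor interaction (median -1.42, 22 of 38 lower and 1 higher) and complement and coagulation cascades (median -2.27, 16 of 20 lower and 2 higher). Among the 14 higher were DNA replication (median 0.65, 8 of 33 higher and 0 lower), mismatch repair (median 0.76, 5 of 19 higher and 1 lower), pyrimidine metabolism (median 0.27, 12 of 80 higher and 7 lower) and ribosome biogenesis (median 0.32, 10 of 101 higher and 6 lower). These 7 pathways kept their direction and call after the rescaling. The ribosome pathway itself was lower (median -0.29), but turned to 0.25 and lost its call after the rescaling (adjusted p = 0.057).

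Within the proteasome and ubiquitin list and the chaperone list, groups were chosen after their values had been seen. The 25 proteasome subunits, without activators and an inhibitor, had a median of 0.15, with 7 higher and 2 lower, and the 8 subunits of the CCT chaperonin, which folds actin and tubulin, a median of 0.40, with 6 higher and 0 lower. After host rescaling the medians were 0.61 and 0.86. The 7 muscle markers past the threshold as higher had control means of 0.0533 to 0.367 TPM and ApNPV means of 1.84 to 10.5 TPM, while the 6 that fell had control means of up to 169.7 TPM. Only the ApNPV values could bring these 7 past the filter, so their direction was largely fixed in advance.

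The fall of haemocyte markers may have a technical part. Viral RNA takes up part of each infected library, which would lower every host transcript alike. After removal of baculovirus-source features and rescaling, the median of the haemocyte list was still -1.69, so this dilution is not the whole cause. The 18 markers with a mean of at least 10 TPM changed by -7.44 (prophenoloxidase) to -0.47 (an integrin alpha), and the SD of their log2 changes, 2.01, was 10.2 times their median standard error. The 18 markers thus did not fall equally. Their spread cannot count against a lower share of haemocytes alone, since markers that other cells also express would then fall less. All 20 other lists compared in this way also exceeded 2 times (3.73 to 16.3). By the bounds set for it, the test says nothing where most other lists do so. Such a spread is not particular to haemocyte markers and decides nothing about the cause. A lower share of haemocytes, alone or as part of the cause, a shift between types of haemocyte, a change in expression within them and RNA from other tissues remain open.

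A hypothesis was that transcripts encoded in mitochondrial DNA were lower, relative to control, than nuclear transcripts of the respiratory chain. Over 14 mitochondrially encoded features the mean log2 change was -2.002 ± 0.941 (SD), and over 72 nuclear ones -0.346 ± 0.659. The difference was -1.66. It gives the hypothesis no support, since the hypothesis came from the same values and several of the 14 features are pieces of 1 gene, such as 3 of NADH dehydrogenase subunit 5. Chosen after their values were seen, NADH dehydrogenase subunit 1 stood at 548 ± 44.3 TPM in ApNPV and 2701 ± 183 TPM in control libraries, and cytochrome b at 263 ± 9.65 and 937 ± 23.1 TPM. A lower level of mitochondrial transcripts in infected haemolymph and a different yield of RNA without long poly(A) tails in infected samples, which was not tested, remain open.

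Of the 10 splits of the 6 libraries into 3 against 3, 1, the real one, gave as many changed features (2982, highest other 0), and 1, the real one, as many changed lists (14, highest other 9). With 10 splits the share cannot fall below 0.1, so the number is too small to test chance.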
